A study of Mus musculus with 10 samples.

How the data were processed

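Gene expression was measured in 10 clonal lines of the mouse preadipocyte line 3T3-L1, 5 classed as Low and 5 as High in adipogenic potential. Per the labels' protocols, total RNA was taken from proliferating cells, copied into sense-strand cDNA, labelled with biotin and hybridised to whole-transcript Affymetrix arrays. The deposited values are log2 intensities, 1 value per array and probe set, and RMA is named in the submitters' processing notes without a version. RMA corrects background, makes the intensity distributions of the arrays alike and summarises the probes of a transcript. It forces arrays towards a common distribution, so a change shared by most genes would be removed from these values. The RMA settings, the array annotation behind the summaries and any array batch are not given in the sources used here.

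The table held 34760 probe sets without missing values. The platform annotation used here listed 22961 of them, of which 21640 carried 1 gene symbol and 1321 carried several. The other 11799 were unnamed here. Of the probe sets with 1 symbol, 21553 had a gene ID found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. They stood for 19937 genes, and 954 genes had more than 1 probe set. For these the brightest probe set over all 10 arrays was kept, without use of the groups. A gene was tested when its value exceeded the array's 25th percentile in at least 5 of the 10 arrays, which left 16339 genes and set aside 3598. The RefSeq table also gave the order of genes along chromosomes. No genome build is named in the sources for the arrays, so no coordinates are printed.

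High and Low lines were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Tests were two-sided, and p-values were adjusted over all tested genes by Benjamini and Hochberg's method with a threshold of 0.05. Differences are High minus Low on the log2 scale, and folds are their powers of 2 on the RMA scale. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 37 lists. camera sets a list against all other genes, so its direction is relative to them. Estimated correlations and fry were used as alternatives. Principal components were computed on centred, unscaled genes. Their scores and the Euclidean distances between lines were compared by two-sided exact permutation tests over all 252 assignments of 5 and 5 lines, for which the smallest p is 0.00794. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

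The 37 lists, the tests, most alternatives and the rule for named genes were written before the data were examined. The lists held 1062 different genes, of which 992 had a probe set of 1 gene and 70 did not. They covered adipogenic transcription factors, anti-adipogenic factors, adipose progenitor, mature, brown and beige adipocyte genes, lipid and energy metabolism, signalling pathways, matrix and adhesion, stress and cell cycle programmes, positional and imprinted genes, and markers of other cell types. Because fewer than 10 genes passed the threshold, the rule named the 10 genes with the smallest unadjusted p in each direction, skipping predicted and non-coding transcripts. It also named a fixed panel of 16 genes, up to 4 members of each list past the threshold, and any gene met only by a count of 5 or fewer.

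The gene test was tried on simulated data with the spread of the real genes. For High against Low with 5 arrays each and 16339 genes, 28% of 50 genes changed 1.25-fold were recovered, 84% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold. Of 161 calls, 7 were false. The sets of genes were changed together, which eases the adjusted threshold, and genes were simulated as independent. These rates therefore do not carry over to the real comparison, where 1 gene passed and Vstm2a, at 6.31-fold, did not. Arrays have no counting depth, so the number of lines sets the precision. Each line is 1 array from a separately grown clone, so the spread holds both clonal and technical variation. The alternatives covered the filter, the probe set per gene, normalization between arrays, variance models, array weights, a minimum fold, the leading digit of the clone name and leaving out each line. Removal of the values of neighbouring genes and of a trend with brightness was added after the data were seen.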

Results

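3T3-L1 is a mouse embryonic fibroblast line whose cells turn into fat-storing adipocytes when given a cocktail of insulin, dexamethasone and IBMX. Single-colony clones of this line had been grown without reaching confluence, and the response of each line to the cocktail had been tested. Lines that stored little triglyceride were classed as Low and lines that stored much as High. The arrays measured RNA from 5 Low and 5 High lines while they were still proliferating and had not been given the cocktail. The comparison therefore asks which transcripts differed between the classes before differentiation began. Low replicates 1 to 5 were clones 1E7, 2D7, 2F1, 4D11 and 4H4, and High replicates 1 to 5 were clones 3F4, 4D2, 4E3, 5C4 and 5D4. Each clone gave 1 array. The median log2 intensity lay between 7.74 and 7.84 in all arrays. An array's mean correlation with the others across probe sets ran from 0.987 in High replicate 4 to 0.993 in Low replicate 3, and no 2 arrays were duplicates.

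Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, was the 1 gene past the threshold between High and Low lines. Its signal (Entrez gene 57875, probe set 10450038) rose from 9.48 ± 0.13 in Low lines to 10.36 ± 0.10 in High lines (SD, n = 5 each). The difference was 0.88 (SE 0.08, 95% confidence interval 0.72 to 1.05), or 1.84-fold, with a limma adjusted p of 0.00118, and all 5 High lines lay above all 5 Low lines. Among 16339 genes tested, 1 was higher and 0 were lower in High lines at an adjusted p under 0.05, and 3 passed at 0.1 (Angptl4, Vstm2a and Gnpat). At an unadjusted p under 0.05 there were 1299 genes, 517 of them higher and 782 lower in High lines. By chance 817 would be expected on average, but the counts of single splits spread widely. Of 99 other splits of the lines into 5 and 5, 16 gave at least 1299 genes, with a median of 651 over the 99 and up to 3768. After centring of the arrays on their medians this split was 640 higher and 510 lower. The 5 High and 5 Low values of 256 genes did not overlap, 1.57% of those tested, where chance gives 0.794%.

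The call of Angptl4 did not hold with the leading digit of the clone name as a block, where the difference was 0.72 and the limma adjusted p 0.785. Only names starting with 4 occur in both classes, so this difference rests on those lines alone, 2 Low and 2 High. A fit of those lines alone gives the same 0.72 by construction (limma adjusted p = 0.393) and is no second result. Without High replicate 5 the number of genes past the threshold went from 1 to 19, and Angptl4, Vstm2a, Pparg, Fabp4, Mest, Hspa4l, Foxc2 and Gnpat were among them.

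The next higher genes by p did not pass the adjustment. Their values separated the lines, but they were picked by p for this comparison, so the separation follows largely from the choice. Vstm2a, which encodes a secreted protein with an immunoglobulin domain, had a signal of 7.58 ± 0.39 in Low and 10.24 ± 0.91 in High lines (SD, n = 5), a 6.31-fold difference with a limma adjusted p of 0.0756. Pparg, the central transcription factor of fat cell differentiation, measured 11.41 ± 0.21 in Low and 12.02 ± 0.19 in High lines (SD, n = 5). Its difference of 0.62 (95% confidence interval 0.37 to 0.86), or 1.53-fold, had a limma adjusted p of 0.255 over all genes and 0.00209 adjusted over the fixed panel alone. All 5 High lines exceeded all 5 Low lines for Pparg (exact permutation p = 0.00794, the smallest possible). Mgst1, a microsomal glutathione transferase, differed 2.22-fold and Gda, guanine deaminase, 2.30-fold. Plin4, which coats lipid droplets, differed by 0.77 and the protease inhibitor gene Serpinb9b by 0.75. Lhfpl2 differed by 0.49, the innate immune receptor gene Tlr2 by 0.46 and the orphan receptor gene Gprc5b by 0.40. The limma adjusted p was 0.243 for Mgst1 and 0.255 for the other 6 of these genes. Pparg and Mgst1 lie on chromosome 6, where the median difference over 827 genes was 0.064.

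**Figure D1:**
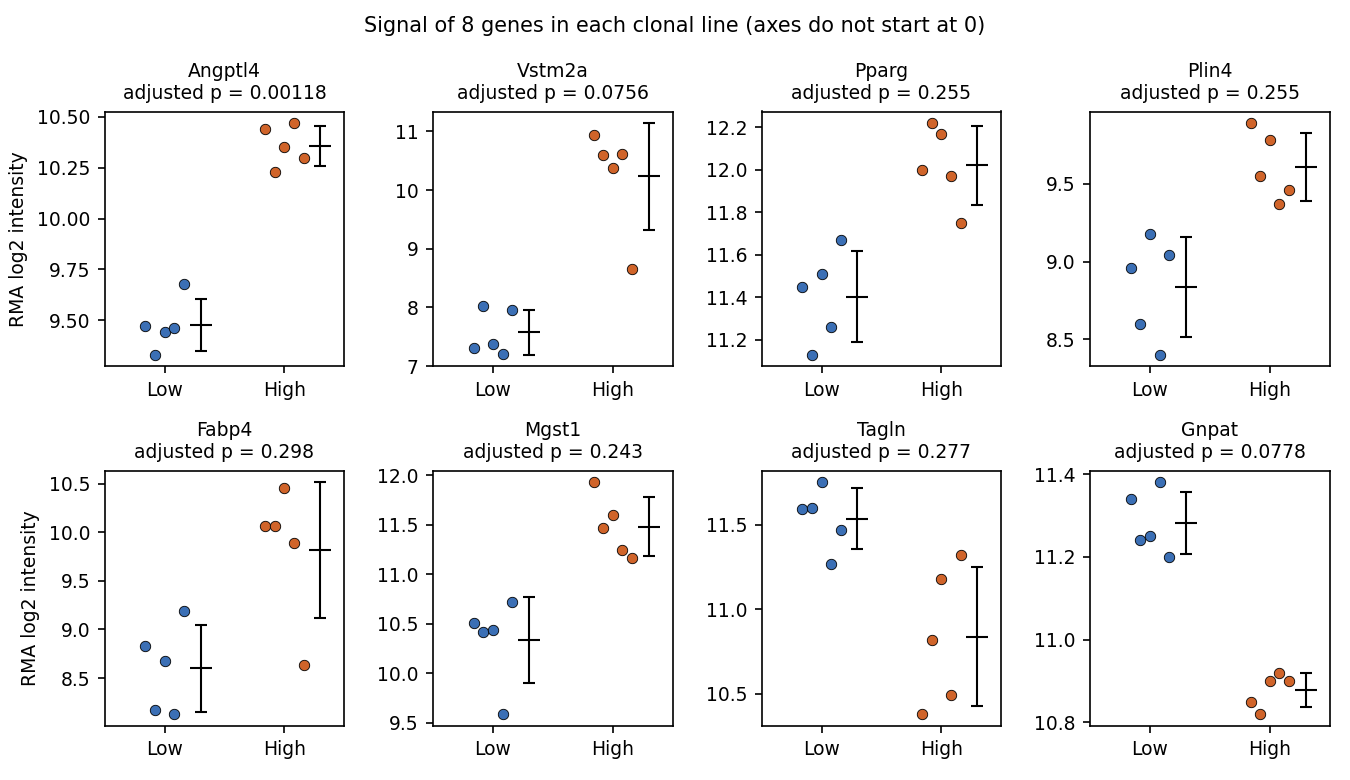
RMA log2 intensity (y axes, which do not start at 0) of 8 genes in each of the 5 Low (blue) and 5 High (orange) lines, with the mean and SD of each class beside the points and the limma adjusted p above. Angptl4 lies at 9.33 to 9.68 in Low and 10.23 to 10.47 in High lines, and for Vstm2a and Fabp4 High replicate 5 lies below the other High lines.

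On the other side, none of the 10 genes with the smallest p passed the adjustment. Gnpat, a peroxisomal enzyme of ether lipid synthesis, measured 11.28 ± 0.08 in Low and 10.88 ± 0.04 in High lines (SD, n = 5), a difference of -0.40 with a limma adjusted p of 0.0778. Foxc2, a forkhead transcription factor, differed by -0.47 (adjusted p = 0.243 in limma). The heat shock protein gene Hspa4l differed by -0.69, Tmem144 by -0.78, the small GTPase gene Rhob by -0.59 and Pik3cb, a catalytic subunit of phosphoinositide 3-kinase, by -0.43. Rbm34, Afg3l1, the nuclear pore gene Nup133 and the cell polarity gene Pard3 differed by -0.33, -0.34, -0.31 and -0.38. Their limma adjusted p was 0.243 for Rbm34 and 0.255 for the others after Foxc2. Gnpat, Foxc2, Rbm34, Afg3l1, Nup133 and Pard3, 6 of these 10, lie on chromosome 8, where 175 of 851 genes were lower and 9 higher at an unadjusted p under 0.05. With the median of its 50 nearest genes subtracted, Foxc2 differed by -0.42, Gnpat by -0.28, Pard3 by -0.25, Afg3l1 by -0.23, Rbm34 by -0.20 and Nup133 by -0.19.

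Among the fixed panel of genes known from adipocyte and preadipocyte biology, 14 of 16 were tested and 0 passed over all genes. Adjusted over the panel alone, Pparg and Fabp4 passed. Fabp4, the fatty acid binding protein of adipocytes, measured 8.60 ± 0.45 in Low and 9.82 ± 0.69 in High lines (SD, n = 5), a 2.33-fold difference with a limma adjusted p of 0.298 over all genes and 0.0127 over the panel. High replicate 5 measured 8.63, within the Low range of 8.13 to 9.19. The progenitor marker Pdgfra differed by 0.33 (limma unadjusted p = 0.0494), and by 0.19 without Low replicate 4, which measured 10.68. The early adipogenic factors Cebpb and Cebpd differed by 0.11 and 0.15, Cebpa by 0.19, Zfp423 by 0.05 and Ebf1 by 0.10. With 1 line left out, Cebpd ran from 0.04 to 0.25, Cebpa from 0.12 to 0.28 and Zfp423 from 0.02 to 0.08. The preadipocyte factor Dlk1, among the brighter signals at 13.85 in Low lines, differed by -0.04. Lpl differed by 0.21, Sox9 by -0.08, Wnt10b by 0.17, Axin2 by 0.04 and Gata2 by -0.00. With 1 line left out, Lpl ran from 0.12 to 0.34 and Sox9 from -0.16 to -0.01. The sign of Axin2 and Gata2 turned with repeated quantile normalization. Adipoq and Cd36 lay below the intensity filter and were not tested in limma. Adipoq measured 5.92 ± 0.08 in Low and 5.81 ± 0.15 in High lines (SD, n = 5). Cd36 measured 5.22 ± 0.10 in Low and 6.34 ± 0.89 in High lines, with all 5 High lines above all Low lines (exact permutation p = 0.00794). High replicate 5, at 5.39, lay barely above the highest Low value of 5.37.

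Contractile genes, on the list of myofibroblast and smooth muscle genes, were the 1 list of 37 past the threshold, and they were lower in High lines relative to other genes. Of 25 members tested, 19 had negative and 6 positive differences, with a median of -0.092 and a camera adjusted p of 0.000479 in limma. This call did not hold with an estimated correlation (p = 0.0933, adjusted p = 0.944), nor with fry (adjusted p = 0.638). Over all genes 0 members passed, and adjusted over the list alone 1 did. That member was Tagln, which encodes the actin-binding protein transgelin, at 11.54 ± 0.18 in Low and 10.84 ± 0.41 in High lines (SD, n = 5), a difference of -0.70 with a limma adjusted p of 0.277 over all genes and 0.0368 over the list. The tropomyosin gene Tpm1 differed by -0.23, Pdlim7 by -0.22 and the actinin gene Actn1 by -0.18, none past the threshold. With an estimated correlation 0 of the 37 lists passed and 0 had an unadjusted p under 0.05. The number of lists past the threshold was 6 with a stricter filter and 9 without Low replicate 2 or without High replicate 2.

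Mature adipocyte genes held the gene past the threshold but did not pass as a list. Of 28 members tested, 20 had positive and 8 negative differences, with a median of 0.066 and a camera adjusted p of 0.0882 (estimated correlation, adjusted p = 0.944). Angptl4 passed over all genes, and Angptl4, Plin4 and Fabp4 passed adjusted over the list alone. fry's mixed test asks whether members differ in either direction and sets them against no other genes. It gave this list an adjusted p of 7.73e-06, while fry's directional test gave 0.638. Of the 28 members, 4 had a limma unadjusted p under 0.05, Angptl4 at 7.22e-08 among them. The mixed test was not repeated without Angptl4, so it is no separate support for the list. Of 28 adipogenic transcription factors tested, 19 had positive and 9 negative differences, with a median of 0.067 and a camera adjusted p of 0.109. Adjusted over the list alone, Pparg and its dimerisation partner Rxra passed, with differences of 0.62 and 0.29, and 0 passed over all genes. The mixed fry adjusted p of this list was 0.00546 and the directional one 0.638. The camera adjusted p of the mature adipocyte genes was 0.0344 without High replicate 2 and 0.269 without High replicate 4. That of the adipogenic transcription factors was 0.0448 with the stricter filter, 0.0216 without Low replicate 2 and 0.204 without Low replicate 4. Among 29 anti-adipogenic factors the median difference was 0.013 (camera adjusted p = 0.95). Foxc2 alone passed over that list, and the mixed fry adjusted p was 0.0466 for it and for the Hedgehog pathway.

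Another 10 lists, the mature adipocyte genes and adipogenic transcription factors included, had an unadjusted camera p under 0.05 without passing, each higher in High lines relative to other genes. Fibrillar and basement membrane collagens and matrix had a median of 0.10 over 39 genes (adjusted p = 0.0619), and matrix remodelling enzymes and inhibitors 0.061 over 35 genes (adjusted p = 0.0882). MHC class I and antigen presentation had a median of 0.076 over 15 genes and fatty acid oxidation and peroxisome one of 0.064 over 28 genes (adjusted p = 0.0619 for both). The adjusted p was 0.143 for brown and beige adipocyte genes and for skeletal muscle genes, 0.152 for the retinoid pathway and 0.0619 for epithelial and keratinocyte markers of other cell types. With an estimated correlation the adjusted p was 0.948 for skeletal muscle genes and 0.944 for each of the others. With the stricter filter the camera adjusted p was 0.00641 for MHC class I and for fatty acid oxidation. Without High replicate 2 it was 0.00466 for collagens and matrix and 0.0162 for matrix remodelling. Without High replicate 3 it was 0.0186 for epithelial markers. With other lines left out, the same lists moved away from the threshold. Without High replicate 5 the camera adjusted p was 0.175 for MHC class I and 0.231 for fatty acid oxidation. Without Low replicate 1 it was 0.376 for collagens and matrix and 0.399 for matrix remodelling, and without High replicate 4 it was 0.5 for epithelial markers. The brown and beige, skeletal muscle and retinoid lists passed under none of the alternatives.

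The remaining lists lay further from the threshold in camera. For markers of other cell types, the adjusted p was 0.293 for neural and glial cells and for macrophages and leukocytes, and 0.38 for endothelial cells. It was 0.361 for adipose progenitor markers and for cell cycle and replication, 0.372 for cartilage and bone genes, 0.293 for the interferon response, and 0.426 for cell cycle inhibitors and p53 targets and for the insulin and IGF pathway. It was 0.548 for the glucocorticoid and cAMP response, 0.638 for the imprinted gene network, 0.663 for oxidative phosphorylation and for the NRF2 and oxidative stress response, and 0.678 for inflammatory cytokines and chemokines. It was 0.727 for Hox and positional genes, the Notch pathway and the glycolysis and hypoxia response, and 0.765 for cholesterol synthesis. It was 0.214 for the BMP pathway, 0.692 for the TGF-beta and activin response, and 0.95 for the FGF and PDGF pathway, Wnt pathway targets and inhibitors, cell adhesion and cadherins, the Hedgehog pathway, and the unfolded protein response. The camera direction was opposite in sign to the median or the mean difference in the insulin, glucocorticoid, NRF2, TGF-beta, Notch, cholesterol, FGF, Wnt and Hedgehog lists. The median difference over all tested genes was 0.021.

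Single members of these lists passed when adjusted over the list alone and not over all genes. The Wnt ligand gene Wnt5a differed by -0.44 and Rspo2, which encodes an amplifier of Wnt signalling, by -0.60. Inhba, the activin A subunit gene of the TGF-beta list, differed by -0.38, and Id4, a BMP-responsive inhibitor of transcription factors, by 0.58. Mest, an imprinted gene linked to fat tissue growth, measured 6.70 ± 0.13 in Low and 9.29 ± 1.60 in High lines (SD, n = 5), with High replicate 5 at 6.62. Rxra passed over the retinoid list as well. The limma adjusted p over all genes was 0.277 for Wnt5a, Inhba, Id4 and Mest and 0.308 for Rspo2 and Rxra.

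**Figure D2:**
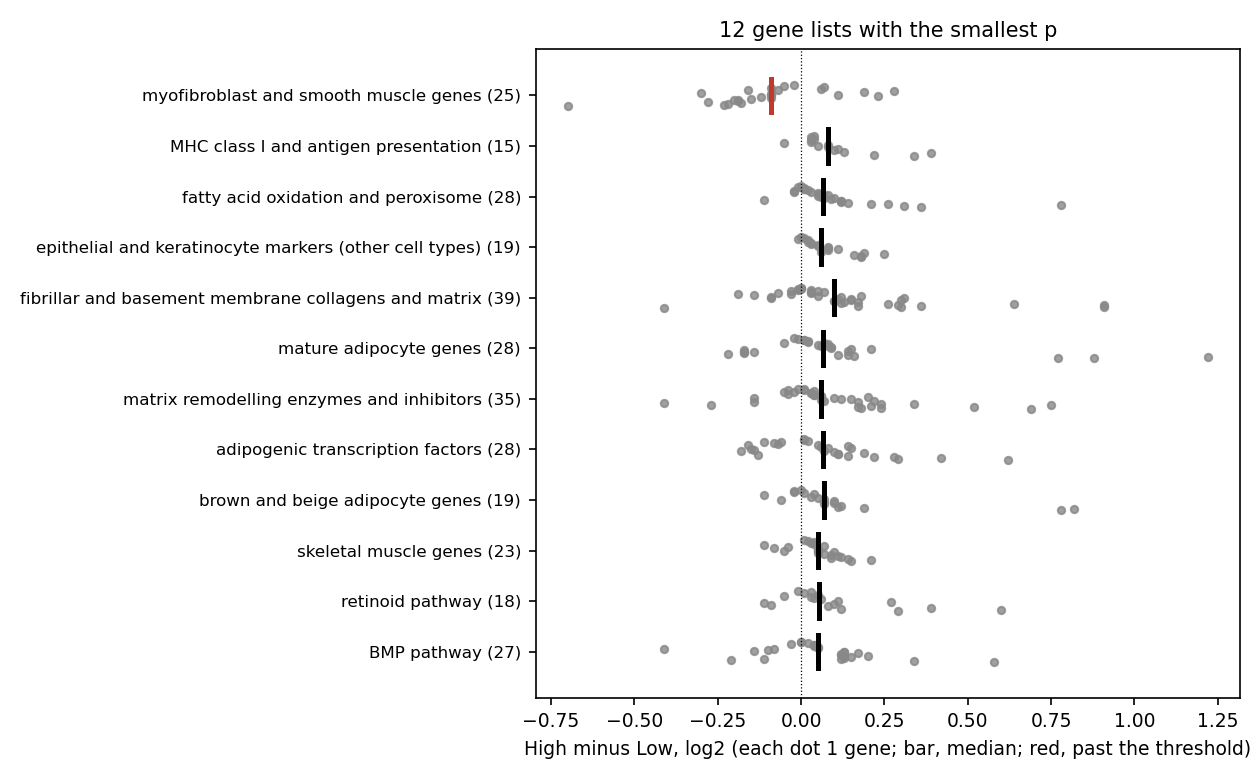
High minus Low log2 difference (x axis) of each tested member (grey dots) of the 12 gene lists with the smallest camera p, with the number of members in parentheses and a bar at the median. Only the myofibroblast and smooth muscle list (red bar, median -0.092) passed the threshold, and it did not with an estimated correlation.

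The next question was whether the main axis of variation between lines followed adipogenic potential. The first principal component held 26.1% of the variance, and its mean score was -6.07 ± 6.58 in Low and 6.07 ± 15.22 in High lines (SD, n = 5). The difference of 12.14 was within the spread between lines (exact permutation p = 0.159, adjusted p = 0.238 over 3 components). High replicate 4 had the highest score, 26.96, and Low replicate 5 the lowest, -13.64. These were also the arrays whose deviations correlated most negatively and most positively with brightness across genes, at -0.48 and 0.36. The components were not recomputed after removal of the brightness trend, so the first component was not separated from that trend. High replicates 3 and 5, at -5.63 and -11.25, lay within the Low range of -13.64 to 0.07. When 1 line was left out, the components were recomputed, so the axis changed, and its sign was set so that High lines scored higher. On these axes the difference was 16.25 without High replicate 4 and 17.20 without High replicate 5 (exact permutation p = 0.0317 for both). Over all lines left out in turn, the exact permutation p ran from 0.0317 to 0.429. The second component, with 17.1% of the variance, differed by 13.18 (exact permutation p = 0.0397, adjusted p = 0.119), and the third by 1.64 (exact permutation p = 0.802).

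**Figure D3:**
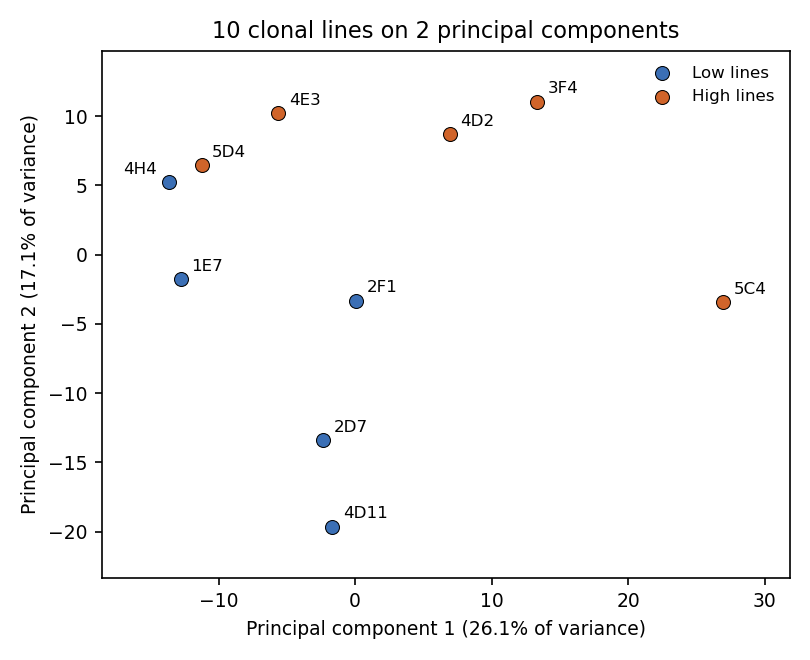
Scores of the 5 Low (blue) and 5 High (orange) clonal lines on the first (x axis, 26.1% of variance) and second (y axis, 17.1% of variance) principal components of 16339 genes. Clone 5C4 lies alone at 26.96 on the first component, and clone 5D4, a High line, lies beside the Low line 4H4.

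High lines were about as far from one another as Low lines. The mean Euclidean distance was 33.28 among Low lines, 34.76 among High lines and 35.85 between the classes. The Low minus High difference of -1.49 was within the spread that relabelling of lines gives (exact permutation p = 0.722). For 2 lines the nearest neighbour belonged to the other class. The nearest line to Low replicate 2 was High replicate 5 at a distance of 33.80, and the nearest to High replicate 5 was Low replicate 5 at 27.72.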

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

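The search for lines far from the others of their class was planned, and the comparison of 2 of its results with High replicate 5's effect on gene counts was made after the results were seen. Of 98 sets of 5 values examined, 5 had 1 line apart from the other 4, where about 4.9 arise by chance.

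High replicate 5 (clone 5D4) stood apart for 2 genes, each time on the side of the Low lines. Its Vstm2a signal was 8.65, against 10.37 to 10.94 in the other High lines, and its Hspa4l signal was 10.26, against 9.56 to 9.73. Without this line Vstm2a differed by 3.05 (limma adjusted p = 4.95e-05) and Hspa4l by -0.81 (limma adjusted p = 0.00728). The line was flagged on these same values, so leaving it out had to enlarge both differences, and these p-values are no added support. With each of the 10 lines left out in turn, the limma adjusted p ran from 4.95e-05 to 0.268 for Vstm2a and from 0.00728 to 0.474 for Hspa4l. Mgst1 measured 9.59 in Low replicate 4, below the 10.42 to 10.72 of the other Low lines. Adipoq, below the intensity filter, measured 5.78 in Low replicate 2 against 5.93 to 5.99 in the other Low lines, and 6.08 in High replicate 4 against 5.71 to 5.80 in the other High lines.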

How the results depend on the processing

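Subtraction of neighbouring genes and removal of the brightness trend were chosen after the results were seen. For 43 named genes, 957 of 985 values under the alternatives kept direction and side of the threshold. Another 12 passed it where the reported value had not, and 14 changed sign. The 2 values that no longer passed were of Angptl4, both by clone-name digit, and rest on the same 2 Low and 2 High lines. For the 11 lists with an unadjusted p under 0.05, 216 of 253 adjusted p kept their side, 35 passed and 2 no longer passed. The number of genes past the threshold, 1 as reported, was 2 with centred arrays and 2 with a mean-variance trend (Vstm2a added), 3 with array weights (Vstm2a and Gnpat added), 6 in lines whose names start with 4 and 0 with the name digit as a block, where 676 genes had an unadjusted p under 0.05. The 6 did not include Angptl4, and that fit rests on 2 lines per class. Leaving out 1 line at a time gave 1 to 19 genes, with 2 without Low replicate 3 (Sned1 added) or Low replicate 5 (Mid2 added) and 19 without High replicate 5.

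The number of lists, 1 as reported, was 6 with the stricter filter, 3 with centred arrays, 4 with repeated quantile normalization, 2 with array weights, 2 after subtraction of neighbouring genes, 4 after removal of the brightness trend, and 0 with estimated correlations or with fry. Leaving out 1 line gave 1 to 9 lists, with 9 without Low replicate 2 or High replicate 2. The group difference on the first principal component ranged from 7.78 to 17.20 with 1 line left out. The component was recomputed each time and oriented so that High lines scored higher, so this difference could not change sign. The difference in distance between lines ranged from -3.96 to 0.87, turning sign without Low replicate 3 (0.35) and without High replicate 4 (0.87), and was 0.22 with the stricter filter. Gata2, at -0.00, was 0.02 with centred arrays, 0.03 with repeated quantile normalization, 0.00 with array weights, 0.09 with the digit block, 0.09 in lines named with 4, 0.03 without the brightness trend, and -0.13 to 0.08 with 1 line left out. Axin2 was -0.01 with repeated quantile normalization and -0.02 without the brightness trend. The cause of these changes was not tested. No paired analysis was possible because the replicate numbers only name the lines in sample order and pair no Low with a High line. The robust prior and the minimum fold do not enter camera and were not run for lists, and Wnt10b, Axin2, Rspo2 and Mest have no value under the stricter filter. No background signal per probe was used here, so dim genes were judged by the intensity filter alone.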

Other observations

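The permutation test of chromosome medians, the test of genes made by mature adipocytes, the chromosome medians after removal of the brightness trend, the stretch at the end of chromosome 8 and the genes of the next paragraph were chosen after the results were seen. The other tests here were set before their results.

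Some genes varied far more between single lines than between the classes, and others set High replicate 5 (5D4) apart from the other High lines. Grb10, an imprinted gene for a growth factor receptor adaptor, measured 11.79 to 12.29 in 7 lines but 6.75 in clone 2D7, 9.19 in 5C4 and 9.53 in 5D4, with a High minus Low difference of -0.09. Mest, also imprinted, measured 6.56 to 6.90 in the 5 Low lines and 6.62 in 5D4, and 9.39, 9.77, 10.93 and 9.76 in the High lines 3F4, 4D2, 4E3 and 5C4. The matrix protein gene Dpt followed a like pattern, at 9.70, 9.94, 10.36 and 10.70 in those High lines and 7.89 in 5D4, against 7.81 to 8.56 in Low lines. Clone 2D7 alone had low Emb, at 4.70, and low Renbp, at 7.44. Over all lines Mest differed by 2.60 and Dpt by 1.59, neither past the threshold in limma. Of 8556 tested probe sets without exactly 1 gene name, 0 passed the threshold in limma and 449 had an unadjusted p under 0.05.

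Chance was not excluded for either headline count. Of 100 splits of the 10 lines into 5 and 5, the real one included, 5 gave at least 1 gene. The highest other split gave 9 genes against 1 in the real one, and it is the real split with clones 2D7 and 5D4 exchanged, so it still follows the classes for the other lines. With 5D4 (High replicate 5) left out of the real classes, 19 genes passed, so the count depends on where this line is placed. For Angptl4 both clones followed their labels, at 10.30 in 5D4 and 9.33 in 2D7, as they did for Pparg, at 11.75 and 11.13, though Angptl4 is named because it separates the labelled classes, and a wrong label of either clone was not excluded. At least 1 list passed in 99 of the 100 splits, with up to 12 in another split against 1 in the real one, so the list threshold with a preset correlation carries little weight here.

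Lower genes in High lines gathered on chromosomes 8 and 12, which held 335 of the 782 genes lower at an unadjusted p under 0.05, 42.8% against 8.54% of the tested genes, while genes of chromosome 6 leaned higher. A trend with brightness is argued against as the whole cause, since the medians of chromosomes 8, 12 and 6 (-0.073, -0.106 and 0.064) were -0.073, -0.108 and 0.048 after its removal, and all 3 lay outside the central 95% of gene lists matched on signal, as did 14 of the 20 chromosomes. Stretches of chromosome with more or fewer copies in single lines may contribute. In 10 of 10 lines, deviations of genes 20 places apart correlated more than in any of 200 shuffles, from 0.040 in 3F4 to 0.170 in 2D7. Shared regulation of neighbouring genes was not separated from copy number, and the brightness trend was not removed from these values. Any grouping of like genes along chromosomes can exceed shuffles of gene order, so this test cannot single out copy number. A chance sorting of lines that differ along chromosomes and a link with adipogenic potential cannot be told apart. The exact permutation p was 0.103, 0.0317 and 0.135 for chromosomes 8, 12 and 6. After adjustment over 20 chromosomes 0 of the 3 passed, where even the smallest p for these 3 alone would have given 0.0529. The last 60 tested genes of chromosome 8, picked because they hold Gnpat, Rbm34, Afg3l1, Nup133 and Pard3, had line medians of 0.003 or more in Low and -0.010 or less in High lines (exact permutation p = 0.00794, not adjusted for the choice).

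Pparg, Angptl4, Plin4 and Fabp4 had higher means in High lines. This set of 4 genes was picked after the values were seen, though Pparg and Fabp4 were on the fixed panel. Angptl4 alone passed over all genes, and Pparg and Fabp4 passed over the panel alone. Neither the mature adipocyte list nor that of adipogenic transcription factors passed in camera as reported (adjusted p = 0.0882 and 0.109). With an estimated correlation the adjusted p was 0.944 for both. The first list passed without High replicate 2 (0.0344) but stood at 0.269 without High replicate 4. The second passed with the stricter filter (0.0448) and without Low replicate 2 (0.0216), but stood at 0.204 without Low replicate 4. Fabp4 in High replicate 5, at 8.63, lay within the Low range. More copies of the Pparg region are argued against as the whole cause of Pparg's difference, which was still 0.53 (95% confidence interval 0.31 to 0.75) after subtraction of its 50 nearest genes, whose median differed by 0.09. Adipocytes already present in the High cultures stay open. A group of 14 genes made by mature adipocytes had a median difference of 0.08, against 0.021 over all tested genes. Its 95% bootstrap interval of 0.03 to 0.12 came from resampled genes and not lines, so it does not measure the spread between lines. These 14 genes leave out Angptl4, Plin4, Fabp4 and Cd36, and 10 of them lay above the intensity filter. The 34 mature adipocyte genes with a probe set went both ways, 24 with positive and 10 with negative differences, with a median of 0.07. Chance stays open for Pparg, Plin4 and Fabp4, none of which passed over all genes.

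High replicate 4 (clone 5C4) had the lowest mean correlation with the other arrays, 0.9872 across tested genes, and the lowest array weight, 0.38. A distortion of its signal with brightness may be the source: its deviations correlated with brightness across genes at -0.48, and after removal of that trend from every array its mean correlation was 0.9884, above the 0.9881 of 2D7. No biological explanation was tested for this line.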
